A study of Mus musculus with 8 samples.

How the data were processed

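RNA-seq libraries were prepared from the hippocampi of 8-week-old C57BL/6 mice, 4 labelled wild type (WT) and 4 labelled Slm2KO. Per the labels' protocols, tissue was flash frozen, RNA was extracted with Trizol and libraries were built from 1 µg of total RNA with the Illumina TruSeq RNA kit. That kit does not mark strand, so reads of overlapping or antisense features cannot be told apart by strand. SLM2 is the protein encoded by Khdrbs3, an RNA-binding splicing regulator of the STAR family.

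The deposited table holds 1 signal value per gene and library, a normalised read count: per the submitters' processing notes, DESeq scaled the reads, and the values are not divided by gene length. The notes also name FastQC, Picard and SAMtools, without versions; the aligner, the counting program and its strand setting are not given in the sources used here. The notes list hg19, a human build, whereas the file header states mm10 coordinates and the gene symbols are those of mouse; coordinates below are mm10 as in the file header. The table lists 56575 features, of which 24338 have a gene symbol; the rest carry only an identifier and took 15.4% to 18.4% of the reads of a library.

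Within each library the deposited signal values were whole multiples of a single step, as counts divided by 1 size factor are, so whole reads could be recovered. In each of the 8 libraries 100% of values came out whole within 0.001 of a read. The step of WT 1 was so close to 1 (size factor 0.999) that it could not be told from rounding by the step alone. Recovered depth ran from 104020058 to 125985224 reads per library, with size factors of 0.928 to 1.11, and mitochondrial features took 10.7% to 12.7% of the reads. The median standard error of a log2 fold change was 0.126. It holds both the spread between libraries and counting error, which were not separated for single features.

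The groups were compared with limma (version 3.58.1, R 4.3.3) on log2(value + 1), with an intensity-trended prior and no covariates, for the 25667 features with a mean value of at least 10 over the 8 libraries. Benjamini-Hochberg adjustment covered all features tested, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, where the added 1 shrinks changes of low genes. Their fitted change can also exceed the fold of the group means, as for Ngp (3.28 fitted, 2.20 from the means). A negative value means lower in the libraries labelled Slm2KO. Single genes also have a two-sided exact permutation test over the 8 values. With 70 assignments its smallest possible p is 0.0286. Intervals are 95% confidence intervals from the limma fit. Simulated data for this comparison held 25667 features. The procedure recovered 6% of 50 features changed 1.25-fold, 42% of 50 changed 1.5-fold, 76% of 50 changed 2-fold and 88% of 50 changed 4-fold. There were 6 false calls among 25467 unchanged features. All changed features were planted in the same data set, which eases the Benjamini-Hochberg threshold. Where few features pass, as in the real data, changes are recovered less often than these rates.

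Gene lists (26) for the SLM2 targets, synapse, splicing, cell types, RNA quality and sex were tested with camera in limma, with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Of 612 list entries, 599 matched a symbol in the table and 598 were tested; the other entries, among them Nlgn3, Vamp1, Junb and Pcp4, were not analysed here. The named genes were set by a rule: Khdrbs1, Khdrbs2, Khdrbs3 and the SLM2 targets; each gene past the threshold if 24 or fewer; the 10 smallest p-values if fewer than 10 genes pass; and up to 3 members with the smallest p from each list without a passing member. Single-gene results for 2 genes that the rule names are not reported here. Other list members are named as examples and were chosen after their values were seen. Groups, tests, lists, the naming rule and most alternatives were set before the data were examined.

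The alternatives were pseudocounts of 0.5 and 10, no filter and a mean of at least 50, edgeR's TMM factors (version 4.0.16), quantile normalisation, edgeR's quasi-likelihood test and DESeq2 (version 1.42.0) on the recovered reads, limma without the trend or with array weights, the replicate number as a block, the series of sample numbers as a covariate, and each library left out in turn. Alternatives chosen after seeing the data used Y-linked reads or Ttr as a covariate, or left out the libraries with the lowest and highest Ttr. Features without a symbol were placed against GENCODE vM21 for the same assembly, whose transcripts also served for searches of shared 30-base stretches. Tables were read and figures drawn with Python 3.11.15 and matplotlib 3.10.9. Splicing was not analysed here: the table gives 1 value per gene.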

Results

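The data describe gene expression in the hippocampus of 8-week-old C57BL/6 mice with 2 genotype labels, WT and Slm2KO, with 4 libraries each. The study asked how overall expression and splicing differ between the genotypes; the gene-level part is given here. The libraries held 104020058 to 125985224 reads. Over all pairs of the 8 libraries, within and between the labels, correlations on the log2 scale were 0.979 to 0.990. No pair of libraries in a group agreed within counting noise (chi-square per degree of freedom of 18.6 to 145). The labels number the samples separately but do not say that each came from a different animal, so p-values measure the spread between these samples.

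Khdrbs3, the gene that encodes the targeted protein SLM2, was not lower in the libraries labelled Slm2KO. Its normalised read count was 22051 ± 2387 in WT-labelled and 29749 ± 3040 in KO-labelled libraries (SD, n = 4 each; chromosome 15, 68928418 to 69101211, plus strand), with each KO-labelled library above each WT-labelled one. The log2 fold change was 0.43 (SE 0.093), which did not pass adjustment in limma (adjusted p = 1.00; exact permutation p = 0.0286). The table holds 1 value for the whole gene, and which part was removed is not given in the sources used here, so it cannot show loss of part of the transcript. Directions below therefore refer to the libraries by their labels. DESeq2 on the recovered reads did call Khdrbs3 higher in the KO-labelled libraries (adjusted p = 0.0191).

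Khdrbs2, which encodes the related RNA-binding protein SLM1, rose 2.26-fold in the libraries labelled Slm2KO and was the only feature of 25667 past the threshold. Its count went from 1096 ± 98.4 to 2481 ± 290 (SD, n = 4 each; chromosome 1, 32172728 to 32657738, plus strand). The log2 fold change was 1.18 (SE 0.099; interval of 1.94- to 2.63-fold; limma adjusted p = 0.00761; exact permutation p = 0.0286). Khdrbs1, which encodes SAM68, the third of these related proteins, was 10685 ± 134 in WT-labelled and 13826 ± 900 in KO-labelled libraries (SD, n = 4; chromosome 4, 129703169 to 129742304, minus strand). Its log2 difference of 0.37 (SE 0.055) did not pass (limma adjusted p = 0.429; exact permutation p = 0.0286), although the groups did not overlap; DESeq2 called it higher (adjusted p = 2.10e-06), as did limma without Slm2KO 4 (adjusted p = 0.0294). The other STAR family members on the list, Qk and Sf1, which act in myelin-related RNA processing and branch point recognition, had log2 differences of -0.04 and -0.07. Adjusted over the list alone, 3 of the 5 STAR genes passed (Khdrbs2, Khdrbs1 and Khdrbs3), against 1 over all genes tested. The list as a set was higher by camera (adjusted p = 2.18e-06), a call lost with an estimated correlation (adjusted p = 0.287 with an estimated correlation).

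Since the groups do not overlap for these 3 genes, their direction in any subset of libraries is fixed and adds no support; the sizes are given for the 2 series of sample numbers, with 2 libraries per label in each, and for libraries with or without Y-linked reads. The log2 differences in the lower and the higher number series were 1.21 and 1.14 for Khdrbs2, 0.42 and 0.32 for Khdrbs1, and 0.51 and 0.35 for Khdrbs3. Without Y-linked reads (3 WT-labelled and 2 KO-labelled libraries) the log2 differences were 1.297 for Khdrbs2, 0.43 for Khdrbs1 and 0.573 for Khdrbs3. With them (1 and 2) they were 1.066, 0.32 and 0.185. The libraries with Y-linked reads all lie in the higher number series, so these divisions overlap. The limma adjusted p of Khdrbs2 exceeded 0.05 without WT 1 (0.0582), WT 4 (0.0767), Slm2KO 1 (0.0527) or Slm2KO 3 (0.0790), and in limma without the trend (0.172), while its log2 fold change stayed between 1.119 and 1.304 over 23 alternatives.

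**Figure D1:**
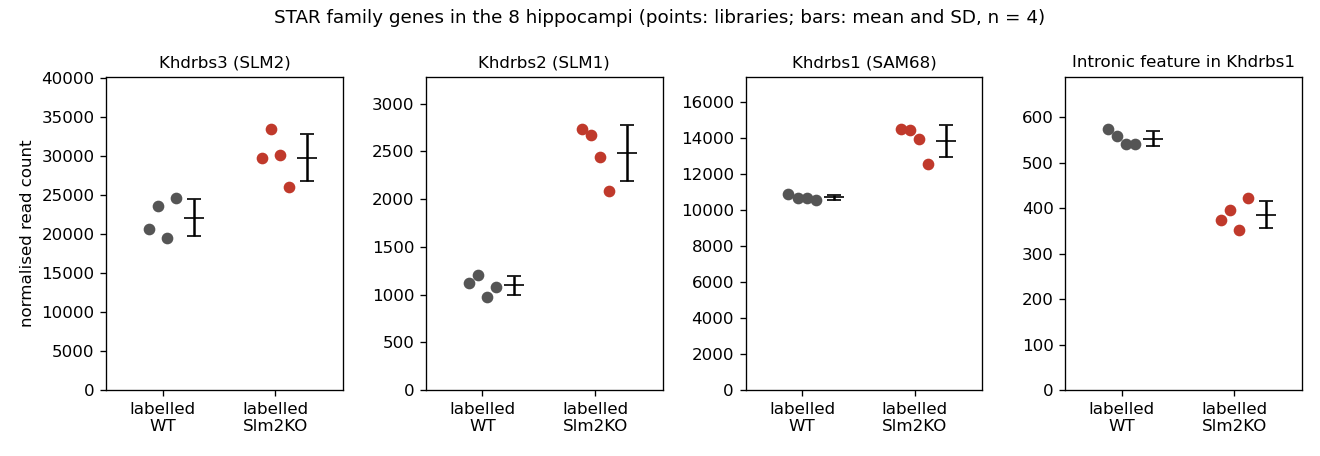
Normalised read counts (y axis) of Khdrbs3, Khdrbs2, Khdrbs1 and an intronic feature of Khdrbs1 in the 4 libraries labelled WT and the 4 labelled Slm2KO; points are libraries, bars are mean and SD. All 3 genes lie higher in each KO-labelled library than in any WT-labelled one, and the intronic feature lies lower.

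Across the transcriptome, 1 feature was higher and 0 were lower in the KO-labelled libraries by limma; 904 features (3.52%) had an unadjusted p under 0.05, with 436 higher and 468 lower. That balance depends on the scaling and the libraries: 568 of 942 were lower with TMM factors, 403 of 996 with quantile normalisation and 1054 of 1623 without the 2 extreme Ttr libraries, and without Slm2KO 3 the count was 596, with 328 lower. For most features the fitted difference was small: for 16867 features (65.7%) the interval excluded a change of 1.5-fold, and for 21859 (85.2%) a change of 2-fold. Groups did not overlap for 642 features (2.50%), where chance gives 2.86%. edgeR's quasi-likelihood test called 1 feature higher and 0 lower. DESeq2 called 6 higher and 3 lower, with 6472 features left without an adjusted p.

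Among the features that did not pass in limma, the 10 smallest p-values were those of Khdrbs1, Khdrbs3, 7 features without a symbol and Itga11, an integrin chain that binds collagen. Itga11 was 645 ± 58.1 in WT-labelled and 444 ± 40.1 in KO-labelled libraries (log2 difference -0.54; SD, n = 4; chromosome 9, 62677855 to 62783979), which did not pass in limma. DESeq2 called 8 of the 10: Khdrbs1, Khdrbs3, Itga11 (adjusted p = 0.00191), GSMG0028771 (5.24e-05), GSMG0028413 (0.000467), GSMG0018663 (0.00191), GSMG0026294 (0.0138) and GSMG0037211 (0.0276), but not GSMG0035022 (0.0572) or GSMG0043318 (0.703). The 7 without a symbol can share reads with any gene they overlap. GSMG0028413, an intronic stretch inside Khdrbs1 (chromosome 4, 129705166 to 129707201), held 554 ± 16.1 and 386 ± 30.4, a log2 difference of -0.52. GSMG0018663 (chromosome 18, 86505750 to 86508239), which overlaps the last annotated exon of Neto1, a kainate receptor auxiliary subunit, was 0.43 higher on the log2 scale, and Neto1 itself 0.10 higher. GSMG0026294 (chromosome 4, 12982156 to 12983244), in an exon of Triqk, was 0.53 higher, with Triqk itself at 0.16. GSMG0035022 (chromosome 7, 110058170 to 110060814), opposite to AA474408, was 0.47 higher. GSMG0028771, on the unplaced scaffold 4_GL456216_random (15881 to 36183), spans the annotated protein-coding gene CAAA01118383.1 and was 0.65 lower (log2 difference -0.65). GSMG0043318 (chromosome 5, 95861155 to 95861802), which overlaps the Gapdh-like processed pseudogene Gm5559 by 89 bases, held 2100 ± 756 in the WT-labelled libraries, and 0, 87.3, 0 and 0 in the KO-labelled libraries (limma adjusted p = 0.310); its fitted difference depends on the pseudocount, and the feature passed with a pseudocount of 10 (adjusted p = 0.0154), with Ttr as a covariate (adjusted p = 0.0397) and without Slm2KO 2 (adjusted p = 3.88e-07). GSMG0037211 (chromosome 8, 39171656 to 39174192), with no annotated gene, was 0.50 higher.

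**Figure D2:**
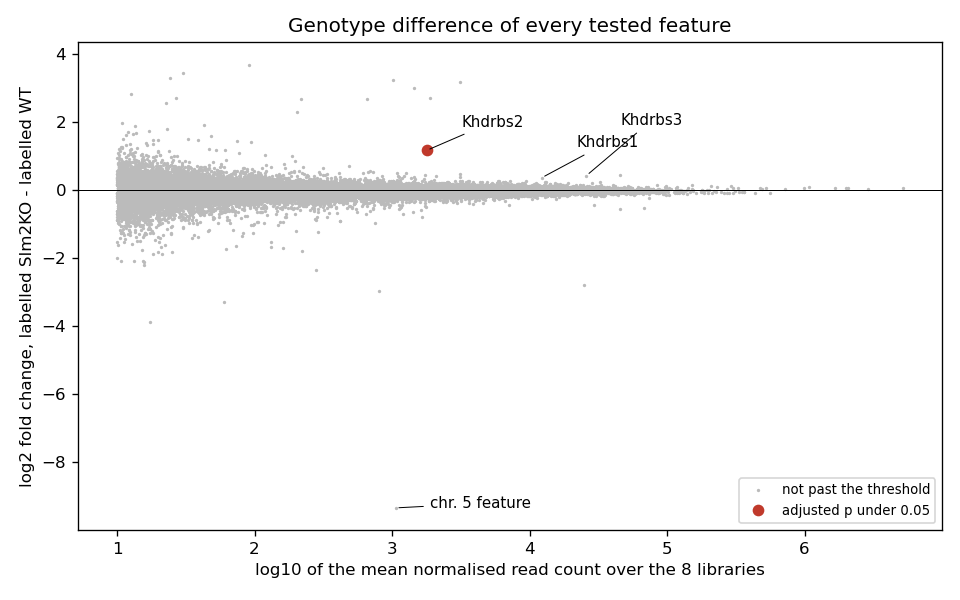
Log2 fold change (labelled Slm2KO minus labelled WT; y axis) against the log10 mean normalised read count over the 8 libraries (x axis) for the 25667 tested features. Khdrbs2 is the only red point (adjusted p under 0.05, log2 fold change 1.18); Khdrbs1, Khdrbs3 and the chromosome 5 feature are named and did not pass.

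Genes whose splicing SLM2 is known to control did not differ detectably in total expression between the labels. The presynaptic adhesion genes Nrxn2 and Nrxn3 had counts of 5056 ± 134 and 14775 ± 1715 in WT-labelled libraries and 4606 ± 489 and 14528 ± 1134 in KO-labelled ones (SD, n = 4). Stxbp5l, a syntaxin-binding protein gene, and Lysmd4, a LysM domain gene, differed by -0.03 and -0.02 on the log2 scale. None of these 4 passed over all genes or adjusted over the list alone, and for each of them the interval excluded a change of 1.5-fold in either direction. The intervals ran from 0.806- to 1.02-fold for Nrxn2 and from 0.861- to 1.13-fold for Nrxn3. The sign of Nrxn3, Stxbp5l and Lysmd4 changed when single libraries were left out. The log2 difference of Nrxn2 then ran from -0.188 without Slm2KO 1 to -0.064 without Slm2KO 4. The list came from the known targets of SLM2, so it is not independent of the study's question. As a set it did not pass (camera adjusted p = 0.316).

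Splicing regulators and synaptic genes showed no member past the threshold. Among 40 neuronal splicing regulators, Srsf3 and Srsf10, serine/arginine-rich factors, had log2 differences of 0.13 and 0.16 and Ptbp2, a repressor of neuronal exons, 0.11; 18 of the 40 were positive and 22 negative (camera adjusted p = 0.350). Of 35 neurexin ligands and other synaptic organizers, 24 were negative (adjusted p = 0.233), with Cbln3 at -0.40, Clstn2 at -0.14 and Ptprf at -0.13. The 25 AMPA and kainate receptor genes included Grik3, a kainate receptor subunit, at -0.18, Shisa7 at -0.24 and Cacng7 at -0.14 (adjusted p = 0.0915). Of 26 NMDA receptor and postsynaptic scaffold genes, 22 were negative, among them Grin2c at -0.17, Homer3 at -0.09 and Shank2 at -0.12, and the list fell as a set by camera (adjusted p = 0.0253; adjusted p = 0.793 with an estimated correlation). That direction turned when Slm2KO 4 was left out (adjusted p = 0.571), and without both the lowest and the highest Ttr library the list was higher (adjusted p = 0.0365); the call was also lost without WT 2 (0.554), WT 4 (0.149) or Slm2KO 3 (0.0800), in limma without the trend (0.0652) or with array weights (0.216), and with Y-linked reads as a covariate (0.238). The 19 GABA and glycine receptor genes, with Gabbr2 at -0.16, Gabra3 at 0.21 and Gabrb1 at -0.10, did not pass (adjusted p = 0.960; median -0.01, while camera gave the direction as up), nor did the 48 presynaptic release genes, with Cplx2 at -0.16, Cacna1b at -0.13 and Synpr at -0.12 (adjusted p = 0.453). Immediate early genes went both ways: Ptgs2, a prostaglandin synthase induced by activity, was 3347 ± 154 and 2856 ± 114 (SD, n = 4; log2 difference -0.23), Inhba was at -0.29 and Bdnf at -0.16, while Fos was at 0.39 (camera adjusted p = 0.951). No member of these lists passed adjusted over the list alone. Several single values rested in part on Slm2KO 4. Without it Cplx2 was at -0.081, Synpr at -0.043, Shank2 and Cacng7 at -0.063, Gabbr2 at -0.069 and Shisa7 at -0.126. Ptbp2 and Gabra3 moved the other way, to 0.158 and 0.290. Left-out libraries also brought calls: splicing regulators were higher without Slm2KO 4 (adjusted p = 0.00752) or the 2 extreme Ttr libraries (0.000581), neurexin ligands lower without WT 3 (0.0131) or Slm2KO 2 (0.0122) but higher without the 2 extreme Ttr libraries (0.0489), AMPA and kainate genes lower without WT 1 (0.0254), WT 3 (0.0140), Slm2KO 1 (0.0359) or Slm2KO 2 (0.00193), and presynaptic genes lower without WT 3 (0.0307) or Slm2KO 2 (0.00488) but higher without Slm2KO 4 (0.00752) or the 2 extreme Ttr libraries (2.79e-05). These calls used the preset correlation and were not repeated with an estimated one. With all libraries and an estimated correlation, the camera adjusted p of these lists was 0.793 to 0.982.

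Markers of hippocampal neuron types did not pass as single genes. All 17 dentate gyrus granule cell markers were negative, with Prox1, the granule cell transcription factor, at -0.20, Pdyn (prodynorphin) at -0.20, Tdo2 at -0.26, Dsp (desmoplakin) at -0.26 and Calb1 at -0.13; the list fell by camera (adjusted p = 8.41e-07; adjusted p = 0.287 with an estimated correlation). Of 17 CA2 and CA3 pyramidal markers, 14 were negative, with Avpr1b, the vasopressin receptor of CA2, at -0.47, Bok at -0.20 and Cacng5 at -0.28 (adjusted p = 0.0200; adjusted p = 0.661 with an estimated correlation). The 12 CA1 markers had a median of 0.11, with Gpr161 at 0.17, Man1a at 0.08 and Lefty1 at 0.14, and did not pass (adjusted p = 0.204), but passed without WT 4 (0.00195), Slm2KO 4 (0.00221) or the 2 extreme Ttr libraries (0.00274) and with array weights (0.0312), and turned without WT 3 (0.275; Gpr161 at 0.0170, Man1a at 0.00563 and Lefty1 at 0.0142). The 24 GABAergic interneuron markers lay near 0, with Slc32a1 (the vesicular GABA transporter) at -0.10, Nxph1 at 0.08 and Vip at 0.19 (adjusted p = 0.952). Adjusted over the list alone, no marker of these 4 lists passed. The CA2 and CA3 call was lost without WT 2 (0.111), WT 3 (0.0971), Slm2KO 3 (0.0837), Slm2KO 4 (0.112) or both extreme Ttr libraries (0.290) and with Y-linked reads as a covariate (0.0853).

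Glial and vascular markers were mostly negative in the KO-labelled libraries, in list calls that did not hold with an estimated correlation. Of 20 astrocyte markers 16 were negative, with Aqp4 (the water channel) at -0.20, Slc4a4 at -0.11 and Gfap at -0.12 (camera adjusted p = 0.0140; 0.661 as the adjusted p with an estimated correlation). Of 20 oligodendrocyte and myelin markers 17 were negative, with Fa2h at -0.20 and Myrf at -0.21 (adjusted p = 0.00132; adjusted p = 0.661 with an estimated correlation). Of 13 precursor markers 11 were negative, with Pdgfra at -0.13, Tnr at -0.14 and Sox6 at 0.10 (adjusted p = 0.0449; adjusted p = 0.588 with an estimated correlation). Of 20 microglia markers 16 were negative, with Trem2 at -0.17, Fcrls at -0.14 and Olfml3 at -0.28; Olfml3 passed adjusted over the list alone, the only member of these 5 lists to do so (list adjusted p = 0.00151; adjusted p = 0.661 with an estimated correlation). Endothelial and mural markers were negative for 20 of 21, with Pecam1 at -0.30, Tie1 at -0.29 and Ly6a at -0.12 (adjusted p = 0.000219; adjusted p = 0.661 with an estimated correlation). No member of these 5 lists passed over all genes tested. Astrocyte, microglia, precursor and endothelial calls were lost without the 2 extreme Ttr libraries (adjusted p = 0.101, 0.112, 0.0502 and 0.0502), the astrocyte call with array weights (0.137), and the precursor call with a mean of at least 50 (0.0519) or without the trend (0.0763). Single left-out libraries also ended calls: WT 1 for endothelial markers (0.0894; Pecam1 at -0.178 and Tie1 at -0.175), WT 3 for astrocytes (0.145) and oligodendrocytes (0.0971), WT 4 for astrocytes (0.124), oligodendrocytes (0.0590) and microglia (0.0644), Slm2KO 4 for astrocytes (0.233) and microglia (0.132), and for precursors WT 2 (0.0534), WT 3 (0.0971), WT 4 (0.231), Slm2KO 1 (0.139) and Slm2KO 2 (0.0960).

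**Figure D3:**
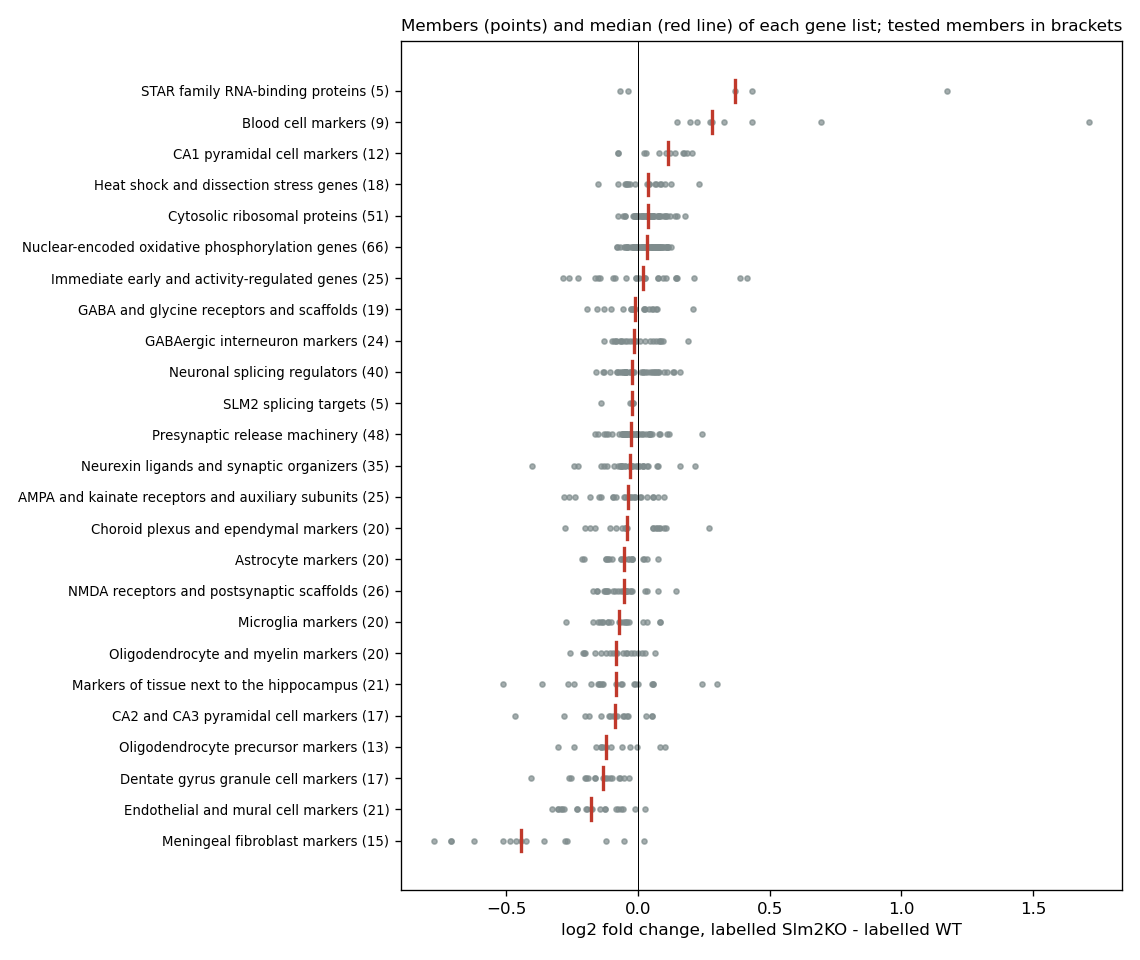
Log2 fold change (labelled Slm2KO minus labelled WT; x axis) of each tested member (points) of 25 gene lists (y axis, sorted by median) and the list median (red line); the sex-linked list is left out. The STAR family has the highest median (0.37) and the meningeal markers the lowest (-0.44).

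Choroid plexus transcripts varied between libraries far more than between genotypes. Ttr, transthyretin made by choroid plexus epithelium, ranged from 219052 in WT 2 to 2262370 in Slm2KO 4, a 10.3-fold range, with both groups spread over it. The first principal component (29.2% of the variance) followed log2 Ttr (Pearson r = 0.906, permutation p = 0.00191; Spearman rho = 0.952, permutation p = 0.00114; Benjamini-Hochberg adjusted p = 0.00191 for both; n = 8, the 1 relation computed). Without WT 2 and Slm2KO 4, the libraries farthest from the median, r was 0.990. The component was computed from the same log2 values, with Ttr and the genes that vary with it included. Its sign was set by the library with the highest Ttr, and Ttr was chosen after the data were seen. The relation is therefore partly built in, and its p-values are not those of an independent test. The 20 choroid plexus and ependymal markers did not differ as a set (camera adjusted p = 0.960, direction up with a median of -0.04). Igf2 was at -0.28, Foxj1 at -0.11 and Cldn2 at 0.27, and each sign turned when single libraries were left out. By camera the list was lower without WT 2 (adjusted p = 0.000331), Slm2KO 4 (0.00752) or both, the 2 extreme Ttr libraries (2.34e-13), and higher without WT 3 (0.0296) or Slm2KO 2 (0.0103). These calls used the preset correlation of 0.01 and were not repeated with an estimated one. With all libraries the estimated correlation of the list was 0.905, and the camera adjusted p with it was 0.983. Meningeal fibroblast markers were negative for 14 of 15, with the transporters Slc22a6 at -0.78 and Slc6a13 at -0.71 and the collagen Col1a1 at -0.43; the list fell by camera (adjusted p = 0.000749; adjusted p = 0.661 with an estimated correlation), and the call was lost without WT 1 (0.228; Slc22a6 at -0.442, Slc6a13 at -0.374 and Col1a1 at -0.184) or Slm2KO 2 (0.106). Blood cell markers were positive for 9 of 9, with Hbb-bs at 0.28, S100a9 at 0.70 and Ngp at 1.71 (adjusted p = 0.00335; adjusted p = 0.661 with an estimated correlation), a call lost without WT 4 (0.128; S100a9 at 0.315 and Ngp at 0.937) or Slm2KO 2 (0.628; Hbb-bs at 0.045) and with a mean of at least 50 (0.05001). Among the blood cell markers, Ngp and S100a9 had low counts. In WT-labelled libraries Ngp was at 0 to 14.2 and S100a9 at 11.5 to 56.0. For Ngp the fold of the group means was 2.20, against a fitted 3.28. Markers of neighbouring tissue, such as Rspo1 at -0.24, Tnnt1 at 0.30 and Cux2 at -0.15, did not pass as a list (adjusted p = 0.238). No single member of these lists passed over all genes or adjusted over the list alone.

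**Figure D4:**
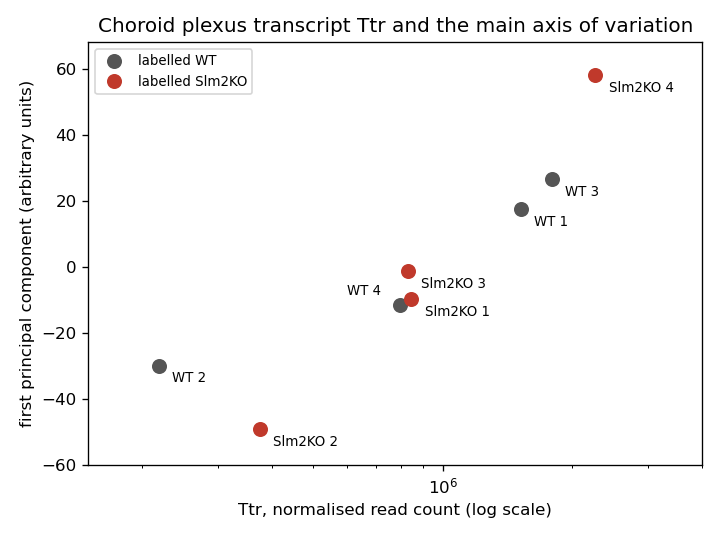
First principal component of the log2 values (y axis, arbitrary units) against Ttr, normalised read count on a log axis (x axis), for the 8 libraries, coloured by label. Both groups tend to rise with Ttr, from WT 2 and Slm2KO 2 at low Ttr to Slm2KO 4 at the highest (r = 0.906). At the low end Slm2KO 2 lies below WT 2 (-49.3 against -30.0) despite its higher Ttr.

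As gene lists, signs of RNA quality differed little between the labels. Slm2KO 4 was at the extreme of several library measures. It had the lowest depth (104020058 reads), Gapdh count (48000) and array weight (0.383, against 0.898 to 1.61 in the others). Its shares of reads in mitochondrial features (12.7%), features without a symbol (18.4%) and the top 10 features (17.7%) were the highest. Whether this underlies results that rest on Slm2KO 4 was not tested. The 51 cytosolic ribosomal protein genes had a median log2 difference of 0.04 (adjusted p = 0.00123; adjusted p = 0.793 with an estimated correlation), with Rps21 at 0.15, Rpl37 at 0.18 and Rpl24 at 0.11. The 66 nuclear oxidative phosphorylation genes had a median of 0.03 (adjusted p = 0.00194; adjusted p = 0.793 with an estimated correlation), with Atp5k, Atp5h and Ndufb5 each at 0.11. For each gene of both lists the interval excluded a change of 1.5-fold. Stress genes did not pass (adjusted p = 0.238; 0.00726 without WT 3), with the chaperones Dnajb1 at 0.13 and Hspb1 at -0.15 and the unfolded protein response factor Xbp1 at 0.08. No member of these 3 lists passed over all genes or adjusted over the list alone. The ribosomal call was lost without WT 2 (0.346), Slm2KO 3 (0.306) or the 2 extreme Ttr libraries (0.0502), and the oxidative phosphorylation call without WT 1 (0.207), WT 2 (0.505), Slm2KO 3 (0.208) or the 2 extreme Ttr libraries (0.633) and with Y-linked reads as a covariate (0.123).

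The sex of the animals was not balanced between the labels. Ddx3y, a Y-linked gene, had a normalised count of 4842 in WT 4, 4766 in Slm2KO 3 and 5417 in Slm2KO 4 and at most 1.81 in the other 5, where Xist, the X-inactivation transcript, was between 32977 and 49369. So 1 of 4 WT-labelled and 2 of 4 KO-labelled libraries carried Y-linked reads. The Y-linked genes Eif2s3y and Uty had log2 differences of 3.20 and 3.02 with intervals that spanned 0, and Tsix, the antisense partner of Xist, was at 0.16; the list did not pass (camera adjusted p = 0.204) except without WT 4 (0.0191).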

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

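The tests of the chromosome 5 feature were chosen after its values were seen. In 182 sets of 4 libraries (the named genes and 5 library measures, such as depth and Ttr, in each label group), 7 (3.85%) held a value far from the other 3; chance gives about 5%. Grik3 reached 1446 in WT 2, with the other WT-labelled libraries at 1337 to 1355. Stxbp5l reached 10753 in Slm2KO 2, against 9142 to 9210 in the others. Srsf10 was lowest in Slm2KO 1 at 15925, against 18063 to 18243. Rps21 reached 20390 in Slm2KO 3, against 17349 to 17578. The Y-linked genes Eif2s3y (9093) and Uty (3568) stood out in WT 4, the WT-labelled library with Y-linked reads.

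GSMG0043318, the chromosome 5 feature that overlaps Gm5559, was at 87.3 in Slm2KO 2 and 0 in the other 3 KO-labelled libraries, against 1326 to 2869 in the WT-labelled ones. A candidate explanation is reads of Gapdh shared with near-identical copies: 100% of the 60 30-base stretches in the 89 bases shared with Gm5559 also occur in Gapdh, but the other bases of the 648 were not searched, so the test decides nothing for the whole feature. Gapdh itself was 56165 ± 1309 and 53716 ± 3988 (SD, n = 4). A variant between the mice of the 2 labels, or the genotype, stays open and was not tested.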

How the results depend on the processing

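Tests with Ttr or Y-linked reads as covariates, without the 2 extreme Ttr libraries, and the 3 counts over other splits were chosen after the data were seen. Over 23 alternatives Khdrbs2 kept its direction and passed in 18. The count of higher features was 6 by DESeq2, 0 by limma without the trend and 0 to 2 with a library left out (0 without WT 1, WT 4, Slm2KO 1 or Slm2KO 3; Khdrbs1 passed too without Slm2KO 4, adjusted p = 0.0294, and by DESeq2, adjusted p = 2.10e-06). The count of lower features was 3 by DESeq2, 1 with a pseudocount of 10, 1 with Ttr as a covariate, and 0 to 1 with a library left out (without Slm2KO 2), each time but DESeq2 GSMG0043318. Khdrbs3 was at 0.43 and passed by DESeq2 (adjusted p = 0.0191; range 0.0191 to 1.00). The causes were not tested. Under the replicate block 1 feature was higher and 0 lower, and 13 lists passed. Same-numbered samples correlated at 0.124, 0.323, -0.0654 and -0.122, and only number 2 correlated best with its own partner. The check gave no sign that the numbers pair the samples, but so few pairs cannot exclude it. The lists passing were 13, against 0 with an estimated correlation and 0 by fry (1, the STAR family, by fry in either direction, adjusted p = 0.0256), and 9 to 14 otherwise; features whose interval excluded 1.5-fold were 15622 to 18781.

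Of the 35 splits of the 8 libraries, 9 called at least 1 feature (highest other 3) and 12 at least 13 lists (highest other 16). Chance therefore cannot be excluded for these counts of calls. In 12 splits 1.5-fold was excluded for at least 16867 features (highest other 17212). That count measures small differences, which a split without any effect also gives, so the splits cannot test it. The split that called 3 features divided the lower from the higher series of sample numbers, so the splits do not measure chance alone.

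With 1 library left out, the log2 fold change of 48 of 85 named features moved by over 1.5 times or turned. Khdrbs3 is not among the 85. Its log2 fold change ran from 0.375 without WT 3 to 0.497 without Slm2KO 4, against 0.433 with all libraries. Features with an unadjusted p under 0.05 were 904, against 1501 of 40442 with no filter, 596 without Slm2KO 3 and 1623 without the 2 extreme Ttr libraries. Signs turned as follows, with the cause not tested; list values are camera adjusted p. Without the 2 extreme Ttr libraries Nrxn3 was 0.102, Stxbp5l 0.00546, Lysmd4 0.0262, Cldn2 -0.801 and Tsix -0.0352 on the log2 scale; lists were SLM2 targets 0.516, neurexin ligands 0.0489, AMPA 0.0962, NMDA 0.0365, presynaptic 2.79e-05, immediate early 0.360 and choroid plexus 2.34e-13. With libraries left out the log2 ranges were -0.0845 to 0.0495 for Nrxn3, -0.0875 to 0.0175 for Stxbp5l, -0.0500 to 0.0210 for Lysmd4, -0.67 to 0.00388 for Igf2, -0.305 to 0.0723 for Foxj1 and -0.40 to 0.62 for Cldn2. The list ranges were 0.00752 to 0.922 for splicing regulators, 0.0122 to 0.799 for neurexin ligands, 0.00193 to 0.505 for AMPA, 2.66e-05 to 0.571 for NMDA, 0.158 to 0.750 for GABA receptors, 0.00488 to 0.799 for presynaptic, 0.0603 to 0.799 for immediate early, 0.140 to 0.956 for interneurons, 0.00195 to 0.585 for CA1, 0.000331 to 0.884 for choroid plexus and 0.00726 to 0.981 for stress genes. The GABA receptor list turned with no filter (0.996), TMM (0.929), quantile normalisation (0.920), edgeR (0.981), the replicate block (0.966), the sample number series (0.991) and fry (0.972); fry also turned interneurons and choroid plexus (both 0.972). Presynaptic genes turned with array weights (0.479) and Y-linked reads (0.879). Immediate early genes turned with array weights (0.940), the replicate block (0.940), the number series (0.999), Y-linked reads (0.271) and Ttr (0.892). Choroid plexus turned with quantile normalisation (0.867), edgeR (0.960), DESeq2 (0.851), array weights (0.422), Y-linked reads (0.483) and Ttr (0.0205). Libraries of a group differed by more than counting noise. For single features the spread between libraries was not separated from counting error.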

Other observations

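The tests of the STAR genes and choroid plexus were chosen after the results were seen; the test of the chromosome 15 neighbours was written before its result. Inside Khdrbs1, the intronic feature GSMG0028413 went against its host gene. It equalled 5.18% ± 0.0924 of the Khdrbs1 count in WT-labelled and 2.81% ± 0.387 in KO-labelled libraries (SD, n = 4). The feature was chosen after its value was seen. Gene and feature each separate the groups, in opposite directions, so their ratio had to separate them too. Its exact permutation p of 0.0286, the smallest possible, was therefore fixed and adds no support. Inside Khdrbs3, the intronic feature GSMG0013258 had 37.3 ± 4.398 and 27.3 ± 7.41 (log2 difference -0.47; exact permutation p = 0.0857); its groups overlapped and its interval of -1.01 to 0.08 spans 0, so a difference is not shown. Of 6 features without a symbol inside Khdrbs2, only GSMG0000109 was tested, at 0.19 (10.7 ± 6.74 and 11.4 ± 4.86, SD, n = 4). The other 5 had a mean under 10. Among them GSMG0000111 had means of 1.94 and 2.97 and groups that did not overlap (exact permutation p = 0.0286). In each library but Slm2KO 1 its value stood for the same few reads. The lack of overlap there came from the size factors, so it shows no difference in reads. Reads of introns and exons were not separated by the table.

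Khdrbs1, Khdrbs2 and Khdrbs3 were each higher in all 4 KO-labelled libraries. Reads shared between the STAR paralogs cannot account for this: 0% of each gene's 30-base stretches occur in the transcripts of the other 2. Unequal sex or choroid plexus tissue cannot account for the whole difference either: with Y-linked reads as a covariate the smallest ratio of the 3 log2 fold changes to those without it was 1.00, and with Ttr 1.01. The Khdrbs3 difference was smaller among the 3 libraries with Y-linked reads (0.185), only 1 of them WT-labelled, than among the other 5 (0.573 on the log2 scale). All 3 also lie in the higher series of sample numbers, so the divisions by sex and by series overlap. Whether sex changes the size of the Khdrbs3 difference was not tested. The genotype, the study's own factor, and any unlabelled difference between the groups stay open.

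Ttr and the other choroid plexus genes varied together across libraries of both labels. The median correlation with Ttr of 17 other markers held by no other list was 0.986, with Kl, Folr1, Aqp1 and Otx2 among them. The ependymal markers Foxj1 (0.956), Ccdc153 (0.713), Rarres2 (0.695) and Tmem212 (0.684) had slopes on log2 Ttr of 0.244 to 0.336, against 0.774 to 0.979 for the other 13. The correlation restates the shared variation, so it cannot tell varying amounts of choroid plexus in the dissected tissue from another cause shared by these genes. The values were already scaled for library depth, and the Ttr range was still 8.53 times the range of depth. Depth therefore cannot account for the range of Ttr. No biological explanation was tested.

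A further hypothesis was that a strain-derived segment around Khdrbs3 may change its neighbours. Of 248 features within 10 Mb, 13 (5.24%) had an unadjusted p under 0.05 in limma, against 3.49% elsewhere. Of these 13, 3 were higher in KO-labelled libraries, among them Tatdn1. The rest were lower, among them Cdc42ep1, Mtss1 and Mpst. The share of 5.24% lay at the 90.9 percentile of 1000 runs of neighbouring features on other chromosomes, between the bounds set for and against, so it decides nothing.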
